A study of Homo sapiens with 12 samples.

How the data were processed

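The series profiled AsPC-1, an established human pancreatic adenocarcinoma cell line, by RNA sequencing of 12 libraries made from total RNA with a TruSeq RNA kit, per the labels' protocols. Each library carries a time label of 8, 16 or 24 h, with 4 libraries at each time. The series' title and design text name PTC596 and DMSO as the treatments, whereas the treatment label of every library reads DMSO and the column headings give only a library number. No label used here says which libraries received PTC596. The treatment was therefore not compared, and neither sample order nor expression values were used to assign it. The groups are the 3 times, each of which may hold both treatments, so the spread within a time includes any treatment effect. Replicate numbers 1 to 4 follow accession order within a time and only name a library. Nothing in the labels says that the libraries came from separate cultures, so the p values measure the spread between these libraries, part of which may be technical.

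Reads had been converted with bcl2fastq 1.8.4 and processed with STAR 2.4.0.1, and the genome build was hg19, per the submitters' processing notes, which give no roles. The counting program, the gene annotation and the use of strand were not given in the sources used here. The authors deposited a table of whole-number read counts per gene for the 12 libraries, not normalized, with 23114 genes named by symbol. The authors also deposited a table of TPM values for the same genes and libraries. The TPM columns each sum to 1e+06, and they equalled the counts times one factor per gene and one per library to within 0.026 on the log2 scale. Of the genes in the table, 5647 had a count of 0 in every library, and 0 rows named no gene. Mitochondrially encoded transcripts and TUBB were not analysed here. The reference used for symbols, GC content and transcript length was GRCh38 (GENCODE 29 transcripts and NCBI RefSeq synonyms), which is not the submitters' build, so no coordinates are given.

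Total counts ran from 11396020 to 16928600 per library. Genes were kept by the default count filter of edgeR with the times as groups, which left 12573 genes holding 99.93% to 99.95% of each library's counts. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with time as a factor over all 12 libraries so that the 3 times shared one estimate of the spread. The times differed in spread, as given in the Results, so the shared estimate lies between them. P values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The common biological coefficient of variation was 0.156. The comparisons were 16 h with 8 h, 24 h with 8 h and 24 h with 16 h, plus a test of any change over the 3 times. Levels are given as CPM computed from the deposited counts, per 1e+06 of the library's counts in tested genes scaled by its TMM factor, except that the ranges of epithelial, fibroblast, immune and endothelial markers over the 12 libraries, at the start of the report, are per 1e+06 of all its counts without that factor. They are shown as mean ± SD over the 4 libraries of a time, and fold changes as log2 values with their standard errors (SE).

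Before the data were examined, 28 gene lists with 393 members were fixed, of which 377 were in the table. They covered alpha and beta tubulins, mitosis, G1/S replication, replication-linked histones, the BCL2 family, NF-κB inflammatory genes, immediate early genes, the integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, hypoxia and glycolysis, YAP/TAZ targets, interferon response, ERK feedback, Polycomb complex 1, p53 targets, the circadian clock, heat shock, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis, lysosome and autophagy, metallothioneins, epithelial and mesenchymal genes, and fibroblast, immune and endothelial markers. The 25 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over lists by Benjamini-Hochberg. The correlation estimated per list was the alternative. For some lists it was not above the preset one, with -0.03 for interferon response and -0.01 for clock genes. Where such a list lost its call, a higher correlation was not the reason.

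The genes named were chosen by a rule fixed before the data were examined. For each comparison they were the 10 highest and 10 lowest by log2 fold change among called genes with an average log2 CPM of at least 1 and no overlap between the 2 groups of 4 libraries. Where none passed in a direction, the 3 with the smallest p in it were named and said not to pass. Up to 4 members of each list with the smallest p over the 3 times were named, as were the 15 genes with the largest SD within a time among those with an average log2 CPM of at least 3, with pseudogenes counted but not named. Other list members that were called, and genes said to be chosen afterwards, were named after their values were seen. Some genes that this rule takes are not reported here.

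The spread within a time was described without testing: the SD of log2 CPM within a time pooled over the 3 times, the share of within-time variance on the first principal component beside 100 shuffles of each gene's values within times, and the median SD of each list beside 10000 random lists matched on mean expression. Pairs of libraries of a time were checked for duplicates by a chi-square test over genes with a summed count of at least 20. The statistic per degree of freedom ran from 3.56 to 46.5, far over sampling noise in every pair, so no duplicate was found and all 12 libraries were kept. This does not show that they came from separate cultures. At 24 h it was 3.72 for replicates 1 and 2, 3.56 for replicates 3 and 4, and 41.6 to 46.5 for the other pairs.

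The alternatives were DESeq2 size factors, upper-quartile and library-total scaling, no count filter beyond removing genes at 0, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), 1 or 2 surrogate variables from sva 3.50.0, a fit on the 2 times compared, and leaving out each library in turn. For the list tests the alternatives were the estimated correlation, 1 surrogate variable and left-out libraries. Offsets for GC content and transcript length were added after the data had been seen, and 97.3% of tested genes had both values. Surrogate variables stand in for unlabelled structure and put no library in a group.

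The tests were tried on simulated counts with the real means and library sizes for 24 h against 8 h (12413 genes tested, of which 198 were changed). The quasi-likelihood test made 158 calls, 10 of them false, and recovered 52.3% of genes changed by 1.5-fold, 79.1% of those changed by 2-fold and 92.4% of those changed by 4-fold. It made 0 calls in the unchanged comparison. Camera called the changed list of 20 genes and 0 of 20 unchanged lists. Each simulated gene was drawn independently, so lists whose genes vary together were not tried. In the real data the estimated correlation was 0.04 for cholesterol synthesis, 0.34 for mitosis genes and 0.86 for ribosomal proteins. The simulation thus does not show how often the preset correlation gives false list calls here.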

Results

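Gene expression was measured in AsPC-1 cells, a human pancreatic adenocarcinoma line, at 8, 16 and 24 h, with 4 libraries per time. The series concerned PTC596 (unesbulin), a small molecule first described as lowering the Polycomb protein BMI1 and known to bind tubulin, against its solvent DMSO. Every library's treatment label read DMSO, so what follows compares the times and describes the spread within them, and each time may hold both treatments. Total counts per library were between 11396020 and 16928600, and 14078 to 14773 genes had at least 1 count. The 10 most abundant genes took 4.53% to 5.11% of the counts. Several epithelial transcripts were abundant and others were low. KRT8, a simple-epithelium keratin, lay between 4948 and 6452 CPM, EPCAM between 701 and 937 CPM and the surface glycoprotein CEACAM6 between 1261 and 1525 CPM. KRT7 lay between 1.49 and 4.25 CPM, CEACAM5 between 6.51 and 12.7 CPM, and S100P reached at most 1.41 CPM. Of the fibroblast markers, the collagen COL1A1 reached at most 1.1 CPM, while LUM, which encodes the matrix protein lumican, lay between 186 and 295 CPM. Of the immune markers, CD68 lay between 122 and 173 CPM, LYZ between 11.3 and 18.8 CPM and CD14 between 0.965 and 5.97 CPM, and the pan-leukocyte gene PTPRC reached at most 0.206 CPM. The endothelial markers were at most 0.532 CPM, the level of VWF.

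The first comparison asked what changed between 8 h and 16 h. NR1D2, which encodes the clock repressor REV-ERBβ, rose from 26.2 ± 1.5 to 53.2 ± 4.02 CPM (SD, n = 4 per time), a log2 change of 1.02 ± 0.09 (SE), with an adjusted p of 1.73e-04 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. RHOB, which encodes a small GTPase, fell by 0.69 on the log2 scale, from 93.3 ± 5.37 to 57.9 ± 2.77 CPM. MUC17, a membrane mucin, fell by 0.58 from 899 ± 33.1 to 599.9 ± 40.8 CPM. TNS4, a focal adhesion gene, and the transcription factor gene MYC fell by 0.48 and 0.44, with adjusted p of 0.0208 and 0.0475 in the same edgeR test. They were among the 6 genes called, 1 higher and 5 lower, of 12573 tested, and all 6 had no overlap between the 4 libraries of each time. At an unadjusted p under 0.05 there were 1128 genes. The call of TNS4 was lost in 7 and that of MYC in 10 of the 12 fits that left out a library, with highest adjusted p of 0.141 and 0.202. DESeq2 called 105 genes, the fit on the 2 times alone 107, limma-trend on log2(TPM + 1) 15 and on log2(TPM + 0.1) 20, and the fits with 1 and 2 surrogate variables 265 and 495.

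Immediate early genes, which growth factors and stress switch on within minutes, were lower at 16 h than at 8 h as a list. Of 12 measured members 11 had negative changes, with a median of -0.48, and camera gave an adjusted p of 1.05e-06 with its preset correlation and of 0.164 with an estimated one. MYC was the 1 member that fell over all genes tested, and 7 were lower when adjusted over the list alone. The changes of KLF6 (-0.45) and IER2 (-0.47) did not pass over all genes. Genes of the integrated stress response were also lower as a list, with a median of -0.27 over 12 members and an adjusted p of 0.0287, and of 0.164 with an estimated correlation. None of its members was called over all genes, while 4 were lower and 1 higher when adjusted over the list alone. The 23 measured ribosomal protein genes all had positive changes, with a median of 0.12 and an adjusted p of 0.00291, but of 0.891 with an estimated correlation and 0.290 with 1 surrogate variable. Ribosomal replicates 3 and 4 of 16 h stood apart, with mean log2 deviations of 0.10 and 0.12, against -0.06 and -0.10 in replicates 1 and 2 and -0.14 to -0.09 at 8 h. None of these 3 list calls held with an estimated correlation. The stress response call was lost in 4 of 12 fits that left out a library, with an adjusted p of 0.103 without 16 h replicate 2, and the ribosomal call in 1, with 0.0717 without 16 h replicate 4.

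The comparison of 24 h with 8 h gave the most calls. Of 12573 genes, 326 passed, 128 higher and 198 lower at 24 h, with a median absolute log2 change of 0.52 and 30 genes over 2-fold. Among the genes that rose were 2 orphan nuclear receptors of the immediate early class, NR4A2 (log2 change 1.63 ± 0.20, SE) and NR4A1 (1.41 ± 0.33). The stress-induced transcription factor gene ATF3 rose by 2.54 ± 0.55, from 1.1 ± 0.45 to 6.47 ± 4.89 CPM (SD, n = 4 per time). DEPTOR, which encodes an inhibitor bound to the kinase mTOR, rose by 1.79 ± 0.34, from 10.5 ± 1.75 to 36.3 ± 21.98 CPM. CAVIN2, a caveolar coat gene, rose by 1.71, PNRC1 by 1.49, SLC35D3, of a family of nucleotide sugar carriers, by 1.46, the histone gene HIST2H2BE by 1.4, the clock gene PER1 by 1.34 and the cytokine gene CSF1 by 1.15. Their adjusted p values in the edgeR test ran from 5.04e-04 for NR4A2 to 0.0476 for SLC35D3.

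Of the genes that fell from 8 h to 24 h, RHOB went from 93.3 ± 5.37 to 43.8 ± 1.49 CPM (SD, n = 4 per time), a log2 change of -1.09 ± 0.08 (SE), with an adjusted p of 2.75e-06 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. DUSP7, an ERK phosphatase gene, fell from 296 ± 20.2 to 134.9 ± 28.2 CPM, a change of -1.13, and RGS4, a regulator of G protein signalling, changed by -1.06. ZBED2 changed by -1.17, LETM2 by -1.01, the carboxypeptidase gene CPA4 by -1.49, KCP by -1.31, MB21D2 by -1.21 and TMEM92 by -1.07. These 6 genes had adjusted p from 0.00236 for ZBED2 to 0.0448 for TMEM92 in the same edgeR test. The plot of named genes shows each change with its error.

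**Figure D1:**
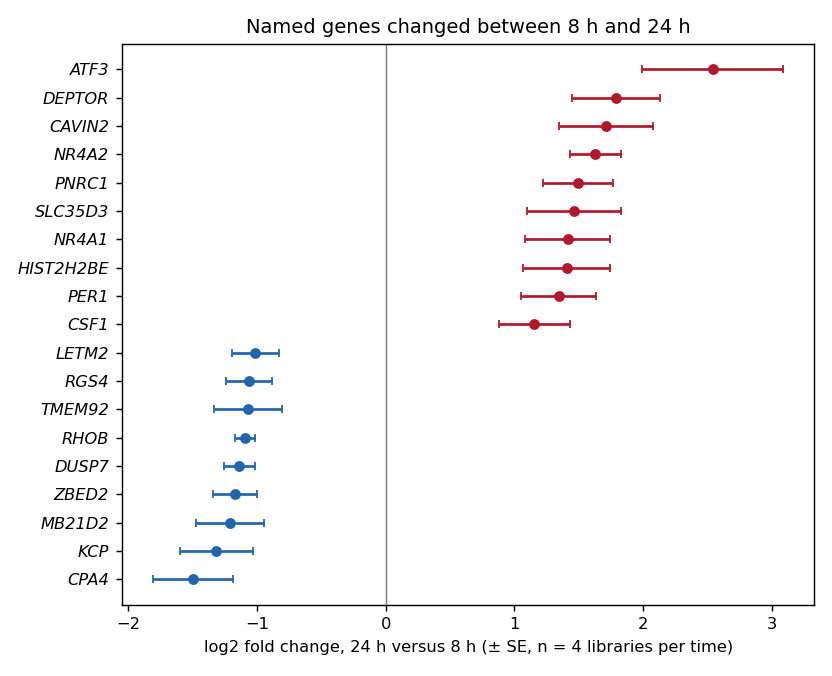
Log2 fold change of the named genes between 8 h and 24 h, with 4 libraries per time; points are the edgeR estimates, bars are ± SE, red is higher and blue lower at 24 h. ATF3 had the largest rise, 2.54, with the widest error bar, and RHOB, at -1.09, had a narrow one.

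Of the 326 called genes 320 had no overlap between the libraries of the 2 times; over all 12573 genes the share was 11.5%, where chance gives 2.86%. At an unadjusted p under 0.05 there were 2222 genes. The count fell to 139, 168, 84 and 118 when 8 h replicates 1, 2, 3 and 4 were left out, and was 158 in the fit on the 2 times alone, 768 by DESeq2 and 1544 and 2365 with 1 and 2 surrogate variables. Scaling by library totals gave 152 genes higher and 152 lower, and the upper quartile 167 and 173, while the sign of all 326 genes was kept. Of 51 named genes called here, 19 kept their call under all 24 alternatives, among them NR1D2, NR4A2, RHOB, DUSP7, RGS4, ZBED2, LETM2, MCL1, IDI1 and SLC2A1. The calls of SLC35D3, TMEM92, UBE2C, HIST2H2BE, IFIT2 and RRP12 were lost most often, each being kept in 10 or fewer of the 24. Those of KLF6, ULK1, ICAM1, ATF3 and NR4A1 were kept in 11, 11, 12, 15 and 15. ATF3, the largest rise, lost its call in 6 of the 12 fits that left out a library.

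Genes of cholesterol synthesis were higher at 24 h. Of 18 measured genes 17 had positive changes and 8 rose over all genes tested (13 adjusted over the list alone). IDI1, which makes the isoprenoid building block dimethylallyl diphosphate, rose from 36.4 ± 3.69 to 64.9 ± 3.53 CPM (SD, n = 4 per time), a log2 change of 0.83 ± 0.09 (SE). HMGCS1 rose by 0.66, DHCR7 by 0.54 and FDFT1 by 0.47, and outside the fixed rule MSMO1 and LSS rose by 0.57 and 0.49. INSIG1, which holds the sterol sensor in the endoplasmic reticulum and is not an enzyme of the pathway, rose by 0.86. The list had a median change of 0.48 and an adjusted p of 1.01e-10 by camera, and of 0.00558 with an estimated correlation. Leaving out any 1 library kept the call.

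Of 15 measured circadian clock genes, 5 rose, 1 fell and 9 did not pass over all genes, and as many rose and fell when adjusted over the list alone. The list was higher by camera with an adjusted p of 0.00599, but of 0.0806 with an estimated correlation. NR1D2 rose by 1.07 ± 0.09 (SE), PER1 by 1.34 ± 0.29 and PER3 by 0.58 ± 0.12, while CLOCK, which encodes an activator of the oscillator, fell by 0.40 ± 0.08. TEF and NR1D1 rose by 0.87 and 0.77; NR1D1 overlaps THRA on the opposite strand, so its reads are uncertain where counting ignored strand. NR1D2 had reached 53.2 CPM at 16 h and stood at 55.2 CPM at 24 h, whereas PER1 was at 4.14, 5.33 and 10.5 CPM and PER3 at 23.7, 24.4 and 35.4 CPM at the 3 times.

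Among survival and signalling genes, MCL1 and BCL2L1, which encode anti-apoptotic members of the BCL2 family, fell by 0.73 ± 0.08 and 0.56 ± 0.07 (SE). MCL1 went from 451 ± 31.8 to 271 ± 28.6 CPM (SD, n = 4 per time). The other 10 measured members of the family did not pass, BID (0.50) and BAD (0.35) included. The family's median was 0.16 and its mean 0.09, opposite to camera's downward direction, which had an adjusted p of 0.697. Adjusted over the list alone, 2 members were lower and 1 higher. ERK feedback genes divided: DUSP4, SPRY4, PHLDA1 and CCND1, which encodes cyclin D1, fell by 0.42, 0.43, 0.42 and 0.47, and the ETS factor gene ETV4 rose by 0.43 (4 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.122). Mean log2 deviations of the ERK feedback list in replicates 1 to 4 were 0.13, 0.07, 0.06 and 0.04 at 8 h and 0.18, 0.16, -0.27 and -0.24 at 24 h, so replicates 1 and 2 of 24 h lay above and replicates 3 and 4 below every 8 h library. SLC7A11, the cystine carrier, and ASNS, asparagine synthetase, were the stress response members that fell, by 0.59 and 0.40, while DDIT3 (0.71) and ATF4 (0.17) did not pass, and the list's adjusted p was 0.122. Immediate early genes had a median of -0.36, with MYC and KLF6 lower (-0.38 and -0.37) and ATF3 higher (4 lower and 1 higher adjusted over the list alone). That list was lower by camera with an adjusted p of 0.0218, but of 0.457 with an estimated correlation, and its call held in 3 of 12 fits that left out a library, with 0.293 without 8 h replicate 1. Its mean log2 deviations in replicates 1 to 4 were 0.56, 0.24, 0.06 and -0.08 at 8 h and -0.20, -0.23, 0.47 and 0.27 at 24 h, so only replicates 1 and 2 of 24 h lay below every 8 h library.

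Single members of other lists fell between 8 h and 24 h. The glucose carrier gene SLC2A1 changed by -0.67 ± 0.09 (SE), the mesenchymal transcription factor gene SNAI2 by -0.74 ± 0.11, the YAP/TAZ target AJUBA by -0.72 ± 0.08, the cochaperone gene DNAJB1 by -0.71 ± 0.12 and LUM by -0.38 ± 0.08. KDM3A, a histone demethylase gene of the hypoxia list, rose by 0.52 ± 0.10. Their lists did not pass by camera: the adjusted p was 0.582 for hypoxia and glycolysis, 0.599 for mesenchymal genes, 0.161 for YAP/TAZ targets and 0.624 for heat shock. The medians of the mesenchymal and heat shock lists were -0.02 and 0.03 while their means were 0.0014 and -0.03. The 2 measured fibroblast markers, LUM and DCN, were too few for a list test. Outside the called genes, ENO2 (0.73) and NDRG1 (-0.20) of the hypoxia list, SNAI1 (1.72, at most 1.54 CPM on average) and FN1 (-0.49) of the mesenchymal list, F3 (-0.66), AMOTL2 (-0.24) and CYR61 (0.30) of the YAP/TAZ list and HSPA8 (-0.35), HSPB1 (0.29) and HSPE1 (0.35) of the heat shock list did not pass.

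Lysosome and autophagy genes were higher as a list (median 0.17, adjusted p = 0.0218, and adjusted p = 0.145 with an estimated correlation). The autophagy receptor gene SQSTM1 and the autophagy kinase gene ULK1 rose by 0.39 and 0.48 (4 higher adjusted over the list alone), and GABARAPL1 (0.83) and CTSB (0.22) did not pass. NF-κB genes were higher with a median of 0.48 and an adjusted p of 0.0379, but of 0.642 with an estimated correlation, 0.0954 with 1 surrogate variable and 0.304 without 24 h replicate 3, and the call held in 7 of 12 fits that left out a library. The list's mean log2 deviations in replicates 1 to 4 were -0.18, -0.17, 0.04 and -0.15 at 8 h and -0.20, -0.26, 0.87 and 0.66 at 24 h, so replicates 1 and 2 of 24 h lay below every 8 h library. TNFAIP2 rose by 0.56 and ICAM1, an adhesion molecule gene near the detection floor at 8 h (0.635 ± 0.400 CPM, SD, n = 4), by 2.12; BIRC3 (0.45) and NFKBIA (0.51) did not pass. Adjusted over the list alone 4 NF-κB genes were higher and 2 lower. Interferon response genes were higher with a median of 0.21 and an adjusted p of 0.0175, but of 0.110 with an estimated correlation and 0.0503 without 24 h replicate 1. IFIT2 rose by 0.36, and IFIT3 (0.35), DDX58 (0.27) and IFIH1 (0.53) did not pass (2 higher adjusted over the list alone). The lysosome call was lost without 8 h replicate 4 (adjusted p = 0.0540).

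Of the replication and growth lists, mitosis genes were lower with a median of -0.08 and an adjusted p of 0.0379, but of 0.645 with an estimated correlation, and the call held in 7 of 12 fits with a library left out (0.154 without 24 h replicate 2). Of 28 members 15 had negative and 13 positive changes. UBE2C, a ubiquitin-conjugating enzyme gene of mitotic exit, fell by 0.94 ± 0.23 (SE), while CCNA2 (-0.34), AURKB (-0.60) and NEK2 (-0.32) did not pass. CCNB2 (0.50), PTTG1 (0.48) and KIF20A (0.45), named after their values were seen, had positive changes that did not pass, and 3 members were lower when adjusted over the list alone. The 7 measured histone genes, of 15 in the table, all had positive changes, with a median of 0.97 and an adjusted p of 0.00276, and of 0.329 with an estimated correlation. Their mean log2 deviations in replicates 1 to 4 were -0.08, -0.11, -0.48 and -0.71 at 8 h and 0.01, -0.09, 1.08 and 0.87 at 24 h, so replicates 3 and 4 of 24 h stood apart. HIST2H2BE was the 1 histone gene that rose over all genes, 5 were higher adjusted over the list alone, and HIST1H2BK (0.70), HIST2H2AC (1.26) and HIST1H2AC (1.13) did not pass. Near the detection floor lay HIST2H2AC and HIST1H2BC, with means of 0.634 and 0.460 CPM at 8 h. Ribosomal protein genes had positive changes in all 23 members, RPS2 (0.21), RPLP0 (0.19), RPL37 (0.27) and RPL30 (0.31) among them, with 0 called. Their list's adjusted p was 7.23e-06, and 0.618 with an estimated correlation, with mean log2 deviations of -0.14, -0.12, -0.09 and -0.09 at 8 h and -0.10, -0.10, 0.30 and 0.27 at 24 h. Reads of these genes can be shared with processed pseudogenes. Ribosome biogenesis genes were lower with a median of -0.08 and an adjusted p of 0.0379, but of 0.645 with an estimated correlation and 0.351 without 24 h replicate 1, and the call held in 8 of 12 such fits. Its mean log2 deviations were 0.01, -0.01, 0.08 and 0.09 at 8 h and -0.26, -0.27, 0.14 and 0.10 at 24 h, so replicates 1 and 2 of 24 h carried the lower values while replicates 3 and 4 lay above every 8 h library. POLR1B and RRP12 fell by 0.34 and 0.32 (2 lower adjusted over the list alone), and WDR43 (-0.24) and NPM1 (-0.0021) did not pass.

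The tubulin and Polycomb lists, chosen for the reported targets of PTC596, did not pass between 8 h and 24 h. This compares times that may each hold both treatments, so it does not bear on an effect of PTC596. All 9 measured alpha and beta tubulin genes had negative changes, with a median of -0.43, 0 called and an adjusted p of 0.122 by camera. TUBA1C (-0.49), TUBB2A (-0.48), TUBB2B (-0.47) and TUBB3 (-0.45) had SE of 0.34, 0.33, 0.36 and 0.28. These SE include a wide spread within a time, described below, with TUBA1C from 2106 to 3878 CPM at 8 h. Reads of TUBA1A, TUBA1B and TUBA1C, and of TUBB2A and TUBB2B, can be shared between near-identical copies, so their single values are uncertain. The 14 measured Polycomb genes had a median of -0.10 and an adjusted p of 0.369, with RNF2 at -0.33, PHC2 at -0.19, PHC3 at -0.09 and PCGF2 at -0.40. BMI1, singled out after its values were seen because it is the reported target, stood at 2.4 ± 0.612, 2.71 ± 0.605 and 2.23 ± 0.234 CPM (SD, n = 4) at 8, 16 and 24 h, and its reads are uncertain because it lies beside COMMD3, with which readthrough occurs. PTC596 was described as lowering the BMI1 protein, whereas these values are mRNA levels. The remaining lists did not pass either. The adjusted p was 0.621 for G1/S replication, 0.711 for p53 targets, 0.369 for endoplasmic reticulum chaperones, 0.582 for metallothioneins, 0.582 for epithelial genes and 0.582 for immune markers. Among their members RRM2 (-0.36), MCM2 (0.33), MCM3 (0.25), SLBP (0.13), BTG2 (1.14), ZMAT3 (-0.92), RRM2B (0.35), CDKN1A (-0.45), HSP90B1 (0.26), HERPUD1 (0.15), CRELD2 (0.15), CALR (-0.13), MT2A (0.48), MT1X (-0.39), MT1E (0.28), MT1G (-0.08), EPCAM (0.26), CDH1 (-0.24), ELF3 (0.79), KRT8 (-0.16), LYZ (0.52), CD68 (-0.22), CD14 (0.42) and DCN (-0.28) did not pass over all genes, the values being log2 changes from 8 h to 24 h.

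**Figure D2:**
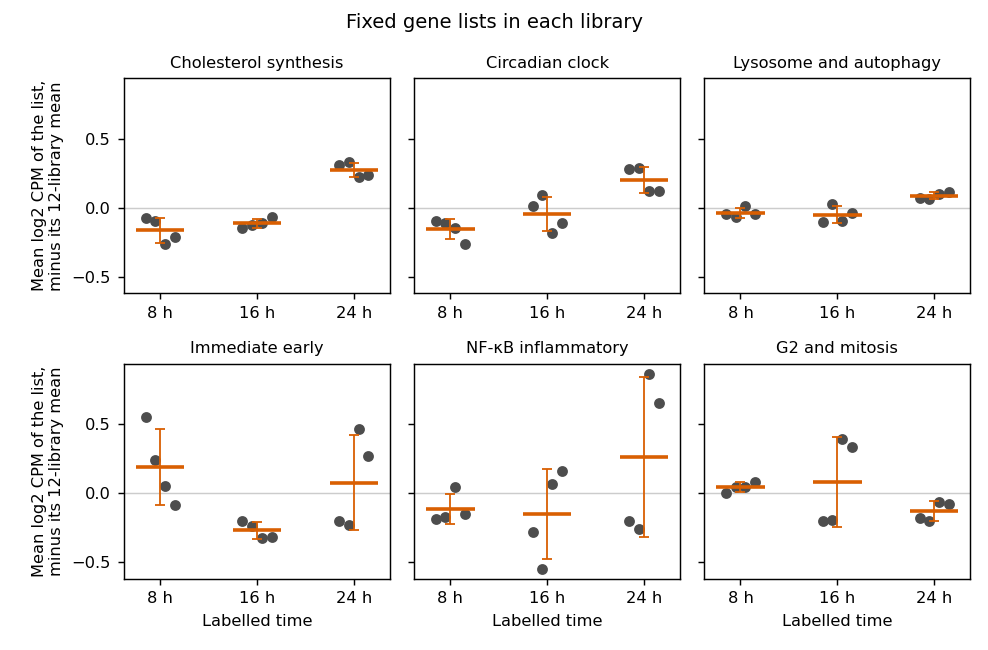
Mean log2 CPM of 6 gene lists in each library, as the difference from the list's mean over 12 libraries, by labelled time; points are libraries (4 per time), orange lines means and bars ± SD. The cholesterol synthesis scores at 24 h, 0.22 to 0.33, lay above all libraries of 8 and 16 h, whereas the NF-κB scores at 24 h ran from -0.26 to 0.87.

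Between 16 h and 24 h a single gene passed. PDGFA, a platelet-derived growth factor chain, fell from 68.0 ± 3.96 to 45.0 ± 2.72 CPM (SD, n = 4 per time), a log2 change of -0.59 ± 0.08 (SE) with an adjusted p of 0.0162 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. No gene was higher. The 3 with the smallest p in that direction did not pass: DHCR7 (0.67, adjusted p = 0.0704), NR4A2 (1.07, adjusted p = 0.140) and IDI1 (0.50, adjusted p = 0.140). At an unadjusted p under 0.05 there were 850 genes. The PDGFA call was lost in 11 of the 12 fits that left out a library and was kept without 24 h replicate 1, and it was also lost under library totals, both TPM scales and the fit on the 2 times alone, with adjusted p up to 0.341. DESeq2 called 51 genes, and the fits with 1 and 2 surrogate variables called 327 and 269.

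Of 25 lists, 10 were higher and 2 lower at 24 h than at 16 h. All 18 cholesterol synthesis genes had positive changes, with a median of 0.40, 13 higher adjusted over the list alone and 0 called over all genes (adjusted p = 6.12e-15, and 0.00158 with an estimated correlation). The call also held with an estimated correlation for lysosome and autophagy genes (median 0.14, adjusted p = 2.51e-04, then 0.0307), interferon response genes (0.19, adjusted p = 0.00332, then 0.0433) and clock genes (0.24, adjusted p = 0.00397, then 0.0433), though with 1 surrogate variable the clock list had 0.0545 and did not pass. It did not hold for the other 8. Higher lists that lost it were NF-κB genes (median 0.39, adjusted p = 9.34e-04, then 0.333), histones (0.77, 8.39e-04, then 0.187), immediate early genes (0.21, 0.00973, then 0.296), ribosomal proteins (0.09, 0.00973, then 0.678), epithelial genes (0.13, 0.0163, then 0.476) and the hypoxia list (0.20, 0.0411, then 0.172). Lower lists that lost it were mitosis (-0.19, 2.51e-04, then 0.397) and ribosome biogenesis (-0.08, 0.0102, then 0.576). Pairs of libraries stood apart in several of these lists. Mitosis scores, as mean log2 deviations in replicates 1 to 4, were -0.20, -0.20, 0.40 and 0.33 at 16 h and -0.18, -0.20, -0.06 and -0.08 at 24 h, so replicates 3 and 4 of 16 h carried the difference. Immediate early scores were -0.20, -0.24, -0.32 and -0.31 at 16 h and -0.20, -0.23, 0.47 and 0.27 at 24 h, so the higher values lay in replicates 3 and 4 of 24 h. The 16 h scores were -0.28, -0.55, 0.06 and 0.16 for NF-κB genes, -0.15, 0.13, 0.05 and -0.52 for histones, -0.06, -0.10, 0.10 and 0.12 for ribosomal proteins and -0.05, -0.09, 0.14 and 0.11 for ribosome biogenesis, beside the 24 h scores given above. Leaving out 1 library also ended the call of NF-κB genes (0.105 without 24 h replicate 3) and of mitosis genes (0.0552 without 16 h replicate 3), and those of the hypoxia, epithelial, ribosomal protein and ribosome biogenesis lists in 4 or more of 12 fits, with adjusted p up to 0.0972, 0.209, 0.596 and 0.309. With 1 surrogate variable the adjusted p was 0.0761 for hypoxia, 0.221 for epithelial genes and 0.380 for ribosome biogenesis. Over the 3 times together 132 genes changed, and 1642 had an unadjusted p under 0.05. That count fell to 48, 68, 40 and 47 without 8 h replicates 1, 2, 3 and 4, to 83, 75 and 86 without 16 h replicates 2, 3 and 4, and was 557 by DESeq2.

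Libraries that shared a time differed more at later times. The median SD of log2 CPM within a time was 0.14 at 8 h, 0.19 at 16 h and 0.23 at 24 h. Of 9421 genes with an average log2 CPM of at least 3, the highest and lowest library were over 2-fold apart for 32 genes at 8 h, 201 at 16 h and 608 at 24 h. The growth lay between replicates 1 and 2 and replicates 3 and 4, not within these pairs. Within them the chi-square per degree of freedom was 7.29 and 4.40 at 8 h, 4.07 and 4.71 at 16 h, and 3.72 and 3.56 at 24 h. For the other pairs it ran from 7.95 to 10.9, from 16.6 to 19.6 and from 41.6 to 46.5. These values were described and not tested. The tests of change gave each gene a single spread over the 3 times. The test of 16 h against 8 h thus also used the 24 h spread, and called 6 genes. The fit without the 24 h libraries called 107. The first principal component of the values centred within each time held 34.1% of their variance and the second 11.6%, while the highest first component in 100 shuffles held 14.3%.

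Alpha and beta tubulin genes had the largest median SD within a time of the 25 lists. It was 0.62, against 0.14 for matched random lists, and none of 10000 random lists reached it. TUBA1B ran from 2600 to 5130 CPM among the 8 h libraries and from 1662 to 4288 CPM among those of 24 h, and TUBB4B from 552 to 1270 and from 350.1 to 974 CPM. TUBA4A, with an SD of 0.81, was among the 15 genes with the largest spread. Some other lists also lay high among their matched lists. The median SD was 0.33 for mitosis genes, 0.31 for G1/S replication genes and 0.43 for immediate early genes, each at the 100th percentile, 0.49 for NF-κB genes at the 99.9th, 0.23 for heat shock genes at the 99.7th and 0.36 for mesenchymal genes at the 98.7th. Replication-linked histones, with 0.49, stood at percentile 44.4, lysosome and autophagy genes, with 0.12, at percentile 1.43, and epithelial genes, also with 0.12, at percentile 10.1.

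**Figure D3:**
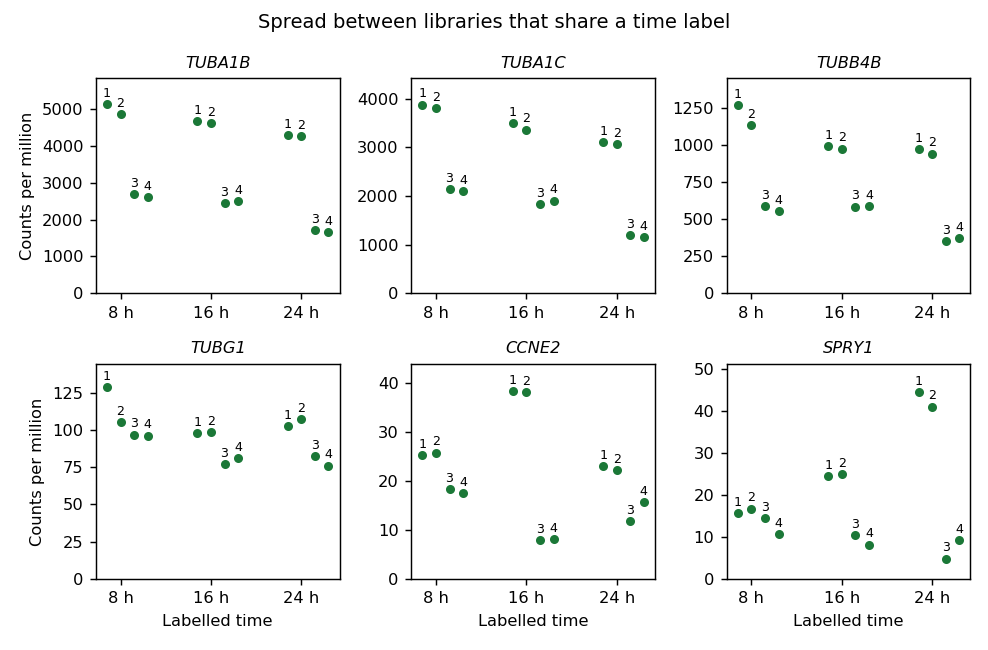
CPM of 6 genes in each library by labelled time; each point is 1 library and its number is the replicate number, a name in accession order. TUBA1B at 24 h ran from 1662 to 4288 CPM, SPRY1 from 4.80 to 44.6 CPM and TUBG1 from 76.1 to 107 CPM, with replicates 3 and 4 the lowest for TUBA1B, SPRY1 and TUBG1.

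The gene with the largest SD within a time was SPRY1, which encodes a Sprouty inhibitor of receptor tyrosine kinase signalling, with an SD of 1.04 and values from 4.80 to 44.6 CPM at 24 h. FOSB (SD 1.01) and FOS (0.75), subunits of the AP-1 factor, ran from 4.07 to 26.7 and from 25.7 to 95.8 CPM at 8 h. FAM111B, RMI2 and CCNE2 were each widest apart at 16 h: FAM111B from 18.3 to 96.9 CPM, RMI2 from 3.50 to 20.6 CPM and CCNE2, which encodes cyclin E2, from 7.84 to 38.4 CPM. The chemokine genes CXCL1 and CXCL8 ran from 3.05 to 14.9 and from 3.38 to 12.2 CPM at 24 h, TGFBR3 from 4.60 to 29.1, ZNF608 from 5.86 to 28.2, C2orf88 from 10.8 to 46.6 and SLC10A7 from 2.96 to 14.7 CPM.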

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

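In 519 groups of 4 libraries (145 genes, 25 lists and 3 library measures at 3 times), 20 had a highest or lowest library whose gap to the next one, as a share of the whole range, passed Dixon's critical value for 4 samples. Chance alone flags about 5% of groups, and 20 is not above that, so no pattern is read from them, and no explanation was tested. Of the library measures, 8 h replicate 3 had 14736 genes with a count, against 14351 to 14406 in the others of that time. Of the lists, NF-κB genes had a mean log2 deviation of 0.0448 in 8 h replicate 3 (others -0.183 to -0.153), and interferon response genes -0.0318 in 8 h replicate 1 (others -0.105 to -0.0989). At 8 h the outlying libraries for single genes were replicate 2 for SLC35D3 (0.491 CPM), NDRG1 (80.3 CPM) and EPCAM (768 CPM), replicate 3 for LUM (260.6 CPM), and replicate 4 for BCL2L1 (405 CPM), AJUBA (66.7 CPM), PHC3 (74.5 CPM) and DCN (0.233 CPM). At 16 h they were replicate 1 for PDGFA (73.9 CPM), CDH1 (69.4 CPM) and BMI1 (1.82 CPM), replicate 2 for CAVIN2 (14.3 CPM), replicate 3 for MYC (209 CPM), and replicate 4 for BIRC3 (34.3 CPM) and RPS2 (3173 CPM). At 24 h they were replicate 2 for GABARAPL1 (9.98 CPM) and replicate 3 for POLR1B (76.2 CPM).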

How the results depend on the processing

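Offsets for GC content and transcript length were chosen after the data had been seen, and all other alternatives before. No replicate block was fitted, because the labels give no replicate numbers and those used here follow accession order. For 16 h against 8 h (6 genes) the count was 105 by DESeq2, 15 on log2(TPM + 1), 20 on log2(TPM + 0.1), 265 and 495 with 1 and 2 surrogate variables, 107 in the fit on the 2 times alone, and 4 to 7 with 1 library left out. For 24 h against 8 h (326 genes) it was 768 by DESeq2, 1544 and 2365 with surrogate variables, which kept all 326 genes, 158 on the 2 times alone, 386 with the GC and length offsets, and 84 (without 8 h replicate 3) to 311 (without 24 h replicate 1). For 24 h against 16 h (1 gene) it was 0 under library totals, both TPM scales and the 2 times alone, 51 by DESeq2, 327 and 269 with surrogate variables, and 0 to 1 with 1 library left out. For any change over the times (132 genes) it was 557 by DESeq2, 1296 and 1959 with surrogate variables, and 40 to 112. Lists passing with an estimated correlation numbered 0, 1 and 4 in place of 3, 10 and 12, 4, 9 and 9 with 1 surrogate variable, and 1 to 3, 6 to 9 and 9 to 14 with 1 library left out. The share of the first component within times was 31.1% to 36.2%, 30.5% with a prior count of 0.5 and 45.1% on log2(TPM + 1). The cause of these differences was not tested. A fit with a library left out or on the 2 times alone has fewer samples. Fewer samples cannot by themselves account for the rise from 6 to 107 genes for 16 h against 8 h. The fit on those 2 times also left out the 24 h libraries, whose spread within a time was the widest.

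Of 128 named results, 58 were called, and none of these 58 changed sign in any alternative run. Of the calls, 4 of 6, 19 of 51 and 0 of 1 held in all 24 alternatives for 16 h against 8 h, 24 h against 8 h and 24 h against 16 h. Among results not called, 4 changed sign between 8 h and 24 h: NPM1 (0.0167 with the upper quartile, 0.0123 with library totals, and -0.0528 to 0.0272 with 1 library left out), MT1G (-0.293 to 0.229), DCN (-0.798 to 0.116) and CD14 (-0.0620 to 0.737). At this depth and with the spread of the main fit, the simulated test recovered 52.3% of genes changed by 1.5-fold. A gene that did not pass is thus not shown to be unchanged.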

Other observations

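The tests of the actin and FOXO lists, of depth, of gamma, delta and epsilon tubulins and of library numbers were chosen after the results were seen, and the corrections for GC content and length after the data had been seen but before their results. From 8 h to 24 h ACTB, the beta-actin gene often used as a control, fell by 0.56 on the log2 scale from 8031 to 5433 CPM, TAGLN2 by 0.37 and VCL by 0.24. Of 24 genes in a list of actin genes and targets of serum response factor, written after such calls were seen, 23 had negative changes, with a median of -0.25, and 4 fell over all genes tested. The list's camera p was 1.62e-06 with a preset correlation but 0.108 with an estimated one, so a change of the list is not shown. Among genes induced by FOXO factors when nutrients or growth factors run low, DEPTOR, FBXO32, HBP1 and IRS2 rose by 1.79, 1.17, 0.94 and 0.64, and 14 of 15 measured members had positive changes, with a median of 0.64. The camera p of that list, written after as well, was 1.90e-07 with a preset and 0.0488 with an estimated correlation. A candidate explanation of both is that growth factor or serum signalling was lower in the culture at later times. Both lists held genes already seen to be called, so neither p decides, and the explanation stays open beside any effect of treatment.

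Of the 35 splits of 8 libraries into 4 and 4, the real one was the only one with as many genes for 16 h against 8 h (6, highest other 0) and for 24 h against 8 h (326, highest other 1). That would exclude a chance arrangement only if the 8 libraries can be exchanged freely, which the structure described next puts in doubt. The third time's libraries also stayed in each fit with their spread. In these 2 comparisons the split of replicates 1 and 2 of both times from the others gave 0 genes, so other splits had little room to give any. For 24 h against 16 h, 2 of 35 splits gave at least the 1 gene called, so chance is not excluded by this count, which also takes the libraries as exchangeable. The other such split, replicates 1 and 2 of both times against the other libraries, gave 4517 genes and every remaining split 0, which points to a structure of the samples that the time labels do not hold. The GC and length offsets kept 297 of the 326 genes called at 24 h against 8 h with their sign, which argues against a bias of that kind as the whole cause of these calls.

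The same structure was seen in single values. Scores on the first component within times were -5.61, -5.64, 4.47 and 6.78 for replicates 1 to 4 at 8 h, -18.6, -20.7, 20.99 and 18.3 at 16 h, and -28.7, -28.1, 28.1 and 28.7 at 24 h. TUBA1B stood at 5130, 4860, 2685 and 2600 CPM at 8 h, at 4677, 4610, 2441 and 2509 CPM at 16 h, and at 4288, 4259, 1712 and 1662 CPM at 24 h. The mean log2 deviations of the 9 tubulin genes were 0.77, 0.57, -0.27 and -0.45 at 8 h, 0.41, 0.44, -0.29 and -0.27 at 16 h, and 0.30, 0.27, -0.79 and -0.70 at 24 h. TUBB6 departed from the rest, with 36.1, 37.7, 40.0 and 44.6 CPM at 16 h and 34.6, 33.3, 47.6 and 49.5 CPM at 24 h. CCNE2 stood at 38.4, 38.1, 7.84 and 8.07 CPM at 16 h. FOSB stood at 26.7, 19.3, 4.07 and 4.11 CPM at 8 h but at 9.29, 8.95, 35.9 and 26.3 CPM at 24 h. BMI1 did not follow this structure at 16 h, with 1.82, 2.88, 3.16 and 3.00 CPM, where only replicate 1 stood apart. BMI1 was higher in replicates 1 and 2 at 8 h, with 2.68, 3.13, 1.93 and 1.86 CPM. At 24 h it ran from 1.92 to 2.43 CPM, with replicates 3 and 4 higher.

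Why alpha and beta tubulin transcripts lay so far apart between libraries of a time was tested in 4 ways. Thinning all libraries to the smallest total, planned first, hardly acts on genes of this level, so its result decides nothing. The 2 pairs of libraries of a time with totals within 5% of each other, both at 16 h, differed in tubulin score by a median of 0.708, against 0.722 over all 18 pairs within a time, which argues against depth as the whole cause. The median SD of 0.62 of these genes was 0.595 after removing each library's trend on GC content and transcript length, which argues against such a bias. A hypothesis is that some libraries of each time came from cells given the tubulin-binding compound named in the series' title, since cells are known to degrade alpha and beta tubulin transcripts when free tubulin rises. The gamma, delta and epsilon tubulin genes, which that feedback is not known to act on, had a median SD of 0.200. That is lower. TUBD1 alone had 0.387, above the 0.292 of TUBB6, but opposite in direction to most alpha and beta tubulin genes at 8 h and 24 h. It stood at 4.92, 7.49, 8.73 and 8.61 CPM at 8 h, 7.12, 8.58, 10.8 and 7.35 CPM at 16 h, and 5.04, 6.71, 9.35 and 10.8 CPM at 24 h. TUBG1, however, was lower in replicates 3 and 4 as they were, so the hypothesis stays open. Its values were 129, 105, 96.9 and 96.1 CPM at 8 h, 97.6, 98.6, 77.2 and 81.0 CPM at 16 h, and 102, 107, 82.6 and 76.1 CPM at 24 h. A batch of culture or library preparation could not be told apart from it, because the widest gap in the tubulin scores lay between the same library numbers at 3 of 3 times, and no label gives the batch or a treatment other than DMSO.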
